A study of Rattus norvegicus with 18 samples.

How the data were processed

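RNA from blood of male Brown Norway and Sprague Dawley rats was hybridised to 18 Agilent 2-colour arrays, design 028279 per the file headers, with 62976 spots each. Per the labels' protocols the blood came from the venous sinus of the eye, total RNA was isolated with Trizol, and RNA was amplified and labelled with a low-input kit of the array maker. Cy5 carried the sample and Cy3 control replicate 1 of the same strain, per the labels. The raw values are the median pixel intensity of each spot and of its local background in each channel, made with Feature Extraction 10.7.1.1 and without normalization, per the file headers. The processed intensities were background-subtracted with spatial detrending and dye-normalized by the same software, per the file headers. The log10 ratios of processed Cy5 over processed Cy3 were made by that software too, per the file headers. The authors also deposited a matrix of log2 ratios with 1 value per probe.

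The scale, centring and direction of the deposited log2 matrix are not stated. Each column lay on a line of slope 1 and r 1 against the scanner's log ratios taken to base 2, so the values are log2 of Cy5 over Cy3 and no gene was centred. The column medians were -0.0140, 0.0135, 0.00266 and 0.000872 for BN control 1 to 4, and 0.0653, 0.0477, 0.0179 and 0.0368 for BN procainamide 1 to 4. They were 0.0210, 0.00510, 0.0173, 0.0121 and 0.0181 for SD control 1 to 5, and 0.0282, 0.0367, 0.0575, 0.0180 and 0.0133 for SD procainamide 1 to 5. The filter by which the authors chose the probes of that matrix is unstated.

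The analysis started from the median spot and background intensities in R 4.3.3 with limma 3.58.1. The design, fixed before the data were seen, had assumed mean spot intensities; only medians are in the deposited scanner output, so medians were used. Background was corrected with normexp (offset 50), ratios were normalized by loess within each array with control spots at weight 0, and spots of the same probe were averaged. Spots that the software marked as non-uniform or as outliers were left out, except for the 0.0741% of probe values with no other spot, where all spots were averaged. Of 30367 probes, 18355 carried 1 gene symbol, and the 26446 with Cy5 well above background on at least 4 of the 18 arrays were tested, representing 13601 named genes. No spot was saturated, and the Cy5 signal was between 27.3 and 48.7 times its background. The median SD of log2 ratios within a group was 0.183 in BN control, 0.212 in BN procainamide, 0.133 in SD control and 0.174 in SD procainamide.

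Each comparison was a contrast in a limma model with a mean for each of the 4 groups over all 18 arrays (14 residual degrees of freedom, moderated by eBayes, 2-sided). P-values were adjusted by Benjamini and Hochberg's method over all probes tested, with a threshold of 0.05. The responses and their difference used log2 ratios. The controls of the strains were compared in log2 Cy5 after loess and Aquantile normalization, since by the labels the strains' references were different RNA. The labels do not say whether each array came from a separate animal, so the p-values measure the spread between these samples. By the labels the array of control replicate 1 compares an RNA with itself. Its log2 ratios had an SD of 0.387 in BN, where the other control arrays had 0.317 to 0.433, and 0.244 in SD, where they had 0.200 to 0.275. With a spread as wide as that of the other arrays, it stays open whether the label of the reference holds. Replicate numbers did not pair control and treated arrays: the correlations of their deviations lay between -0.523 and 0.129.

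A gene was represented by its probe of highest mean intensity in both channels. The genes named were, by a rule fixed beforehand, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap. For the strain difference in response there was no overlap condition. From each fixed list up to 4 members of smallest p were eligible. Some genes that the rule chose are counted but not reported here. The 30 lists covered interferon response, NF-kB and inflammation, T cells, B cells, plasma cells, NK cells, monocytes, neutrophils, erythroid cells, platelets, eosinophils with basophils, MHC class I and II, DNA methylation, methylation-sensitive T cell genes, Th1, Th2, Th17 with regulatory T cells, Toll-like receptors, complement, apoptosis and clearance, cell cycle, immediate early genes, glucocorticoid response, ribosomal proteins, oxidative phosphorylation, drug metabolism, glycolysis with hypoxia, connective with epithelial, muscle and eye genes, and endothelium. They were tested with camera, which compares a list with the other genes, at an inter-gene correlation of 0.01. Counts "adjusted over the list alone" adjust p over the members of 1 list. Camera with an estimated correlation and fry were set beside it. Fry's directional p asks whether the genes of a list move on balance one way, its mixed p whether they move in either direction, and neither compares them with other genes.

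The model was tested on simulated data in which 200 of the probes were changed. The simulated noise was independent between probes and held no effect of slide, scan day or brightness. The shares of false calls therefore do not carry over to the real calls. Variances came from the fit of the ratios, also for the controls. In the BN response 38.8%, 92.5% and 100% of changes of log2 0.5, 1 and 2 were recovered, with 5.52% of calls false. In the SD response 41.8%, 89.6% and 100% were recovered, with 6.10% false. For the strain difference in response 14.9%, 67.2% and 93.9% were recovered, with 4.10% false. For the strain difference in controls 35.8%, 86.6% and 97.0% were recovered, with 3.31% false.

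Other settings, fixed beforehand, were Agilent's processed signals, a normexp offset of 16, median centring, scaling between arrays, Cy5 alone, 2 other filters, a replicate block, slide as a random or fixed block, only 1 strain's arrays or 1 slide's arrays, trend and robust eBayes, array weights, a fold change of at least 2, the authors' matrix, and leaving out each array. Scan day (slide 2 against slides 1 and 3) and array brightness as terms were added after the data had been seen. Lewis rats, named in the study's design text, are not analysed here, and gene positions were not used because no genome was in hand.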

Results

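Gene expression in blood was measured on 18 Agilent 2-colour rat arrays. The animals were male rats of 2 strains, Brown Norway (BN), an inbred strain, and Sprague Dawley (SD), an outbred strain. They received procainamide, an antiarrhythmic drug known to induce lupus-like autoimmunity in some patients, at 40 mg/kg, or sterile water, and blood came from the venous sinus of the eye after treatment. There were 4 BN control, 4 BN procainamide, 5 SD control and 5 SD procainamide arrays. The series asks how rat strains differ in their response to the drug; Lewis rats, which its design text also names, are not analysed here. On every array Cy5 carried the sample and Cy3 a reference of the same strain, which by the labels was control replicate 1. The median Cy5 spot signal lay between 997 and 1986 on the BN control arrays and between 1694 and 3187 on the BN procainamide arrays, and between 1446 and 2876 on the SD arrays. Between 73.4% and 87.1% of probes were well above background in Cy5, and the number of arrays limits the precision. The arrays lay on 3 slides. Slide 1 held the 5 SD control and 3 SD procainamide arrays, slide 2 the 4 BN control and 2 SD procainamide arrays, and slide 3 the 4 BN procainamide arrays. Slides 1 and 3 were scanned on the same day and slide 2 on the next, so the BN groups differed in slide and scan day. A term for scan day could still be fitted through the SD procainamide arrays, under the assumption that slide 3 behaved like slide 1. Its values stand beside each comparison, with those of a term for array brightness, the log2 of the median Cy5 signal.

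The first comparison asked how procainamide changed blood expression in BN rats, with 4 treated and 4 control arrays. Hexokinase 3 (Hk3), which phosphorylates glucose in white blood cells, rose 17.3-fold (log2 4.12 ± 0.32 SE, adjusted p = 4.02e-07). Acod1, which makes itaconate in activated macrophages, rose 29.7-fold (log2 4.89 ± 0.47 SE, adjusted p = 4.31e-06). It was well above background on 2 of the 4 control arrays, so the size of its rise is not exact. Ass1, the argininosuccinate synthase of arginine synthesis, rose 14.6-fold (log2 3.87 ± 0.34), and Cxcl9, a chemokine induced by interferon gamma, rose 8.79-fold (3.14 ± 0.32). Among the genes that fell were members of the tissue kallikrein family, serine proteases best known from glands. Klk1b3 was 14.5-fold lower (log2 -3.86 ± 0.28 SE, adjusted p = 2.61e-07), Klk1c3 7.85-fold (-2.97 ± 0.24), Klk1 7.28-fold (-2.86 ± 0.20), Klk1c8 6.94-fold (-2.80 ± 0.21) and Klk1c2 4.13-fold (-2.05 ± 0.26).

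Other large rises in BN blood were those of Ifng, the gene of interferon gamma (10.8-fold, log2 3.43 ± 0.44), the ubiquitin-like modifier Ubd (6.78-fold, 2.76 ± 0.54), the chemokine Ccl20 (6.17-fold, 2.62 ± 0.19) and complement component C3 (5.23-fold, 2.39 ± 0.25). Zp3, known as an egg-coat glycoprotein, rose 4.84-fold (2.27 ± 0.19) and was well above background on 2 of 4 BN control arrays, so the size of its rise is not exact. The fatty acid receptor Gpr84 rose 4.56-fold (2.19 ± 0.35). Cd209d, a C-type lectin, was 8.32-fold lower (-3.06 ± 0.28), with a signal well above background on 4 of 4 control arrays and 1 of 4 treated arrays. The size of its fall is therefore not exact. Enkur was 5.60-fold lower (-2.49 ± 0.39), the antiviral 2'-5'-oligoadenylate synthetase Oas2 5.03-fold (-2.33 ± 0.30), the beta-defensin Defb14 4.16-fold (-2.06 ± 0.28) and Scart1 4.08-fold (-2.03 ± 0.31). By the rule that chose them, every array of one group lay above every array of the other in these 20 genes. Of the 3105 named genes called in BN, 2206 met that condition. Limma's adjusted p did not exceed 0.00185 in the 20. With scan day as a term all 20 kept their direction and 13 stayed past the threshold. The others were Ifng (log2 3.08 ± 0.73, adjusted p = 0.0626), Ubd (2.91, 0.175), Gpr84 (2.02, 0.147), Enkur (-1.88, 0.204), Oas2 (-1.40, 0.153), Defb14 (-2.02, 0.0556) and Scart1 (-0.77, 0.392). With brightness as a term 19 stayed past it, Enkur being the exception (adjusted p = 0.0510).

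Of the 30 gene lists, 9 shifted higher and 3 lower in BN blood by camera. Fewer than 80% of the genes were measured in the lists of NF-kB targets (16 of 21), plasma cells (7 of 13), erythroid cells (22 of 28), platelets (13 of 18), DNA methylation (8 of 14) and Th17 with regulatory T cells (10 of 14). A test of these 6 as whole lists is void in every comparison; their medians and p-values describe the measured members. Of the 12 shifts in BN, 3 are of this kind (NF-kB, plasma cells and platelets). Genes of MHC class I antigen presentation rose in 10 of 12 measured members (10 adjusted over the list alone), with a median log2 difference of 0.73 (adjusted p = 5.16e-08; adjusted p = 0.145 with an estimated correlation). Tap1, the peptide transporter, rose 2.36-fold, RT1-A2 2.27-fold and RT1-A1 1.88-fold. NF-kB targets and inflammatory cytokines rose in 9 of 16 members (12 adjusted over the list alone; median 0.64, adjusted p = 1.68e-07), among them Tnf (2.44-fold), Il1rn (2.23-fold), Ccl4 (2.22-fold) and the adhesion molecule Icam1 (1.87-fold). Th1 genes rose in 5 of 7 members (6 adjusted over the list alone; median 0.59, adjusted p = 3.37e-05). Beside Ifng these were Cxcr3 (1.73-fold), Il12rb2 (1.69-fold), Stat4 (1.51-fold) and the interleukin 2 gene Il2 (log2 0.36). With an estimated correlation the measured NF-kB targets (adjusted p = 0.0399) and the Th1 list (adjusted p = 0.00977) stayed past the threshold, and no other list did.

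Genes of oxidative phosphorylation rose in 12 of 42 members (18 adjusted over the list alone; median 0.19, adjusted p = 5.51e-06; adjusted p = 0.266 with an estimated correlation), Cox7c by 1.53-fold. NK cell and cytotoxic genes rose in 4 of 16 (4 adjusted over the list alone; median 0.25, adjusted p = 0.00802; adjusted p = 0.378 with an estimated correlation), including Klrc1 (3.87-fold) and the death ligand gene Faslg (2.22-fold). Glycolysis and hypoxia genes rose in 6 of 16 and fell in 2 (8 and 3 adjusted over the list alone; median 0.27, adjusted p = 0.0159; adjusted p = 0.172 with an estimated correlation), with Tpi1 1.64-fold higher and Pfkl 1.64-fold lower. T cell markers rose in 2 of 20 members, Trat1 (1.96-fold) and Cd27 (1.33-fold), which are also the 2 adjusted over the list alone (median 0.17, adjusted p = 0.0159; adjusted p = 0.370 with an estimated correlation). Plasma cell and immunoglobulin genes rose in 3 of 7, Derl3 (1.81-fold), Xbp1 (1.79-fold) and Sdc1 (1.78-fold), also 3 adjusted over the list alone (median 0.23, adjusted p = 0.0397; adjusted p = 0.477 with an estimated correlation). Interferon response genes rose in 6 of 26 and fell in 1 (8 and 2 adjusted over the list alone; median 0.13, adjusted p = 0.0303; adjusted p = 0.60 with an estimated correlation). Here the guanylate-binding protein gene Gbp2 (3.65-fold) and Cxcl10 (1.99-fold) rose while Oas2 fell. The median log2 ratio of the interferon list was higher on BN control 1 (0.46) than on the 4 BN procainamide arrays (-0.14, 0.04, -0.01 and 0.19), and was -0.09, -0.34 and -0.34 on the other BN controls. With 1 array left out the interferon list did not pass without BN control 3 (median 0.06, adjusted p = 0.164), BN control 4 (0.01, 0.0968) or BN procainamide 4 (0.03, 0.0968). The plasma cell list did not without BN control 1 (adjusted p = 0.0593), 3 (0.0593) or 4 (0.137) or BN procainamide 2 (0.140), the T cell list without BN control 3 (0.0702) and the NK cell list without BN procainamide 2 (0.105).

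Lists that shifted lower in BN blood were those of platelets, ribosomal proteins and endothelium. Platelet markers fell in 6 of 13 members (6 adjusted over the list alone; median -0.42, adjusted p = 0.00335; adjusted p = 0.370 with an estimated correlation), among them Gp1bb (1.66-fold), the ADP receptor P2ry12 (1.59-fold) and Gp9 (1.51-fold). Ribosomal protein genes fell in 12 of 46 (14 adjusted over the list alone; median -0.18, adjusted p = 0.00312; adjusted p = 0.370 with an estimated correlation), for example Rpl13 (1.38-fold) and Rpl14 (1.37-fold). Endothelial markers fell in 3 of 8, the cadherin Cdh5 (2.33-fold), Esam (1.56-fold) and Kdr (1.43-fold), and in 4 adjusted over the list alone (median -0.49, adjusted p = 0.00977; adjusted p = 0.196 with an estimated correlation). With scan day as a term 11 of the 12 lists stayed past the threshold, interferon being the exception (median 0.03, adjusted p = 0.0520). MHC class II genes (0.28, adjusted p = 0.0137), apoptosis and clearance genes (0.21, 0.00626) and connective, epithelial, muscle and eye genes (-0.34, 0.0426) passed in addition. With brightness as a term 7 stayed, and the lists of interferon (adjusted p = 0.207), T cells (0.283), plasma cells (0.280), NK cells (0.107) and glycolysis (0.0629) did not, while the connective, epithelial, muscle and eye genes passed (median -0.48, adjusted p = 0.0177). By fry the interferon (adjusted p = 0.123) and plasma cell (0.0613) lists did not pass. It called Th17 and regulatory T cell genes (0.00925) and apoptosis and clearance genes (0.0360) higher. Eosinophil and basophil markers (0.0297), glucocorticoid response genes (0.0344) and connective, epithelial, muscle and eye genes (0.00218) were lower by fry.

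By camera with the groups alone no shift passed the threshold in the remaining lists of the BN response, although single members did. With 1 array left out some did pass: cell cycle genes without BN control 1 (median 0.23, adjusted p = 0.00776), erythroid markers without BN control 2 (-0.76, 0.0142), BN control 4 (-0.60, 0.0456) or BN procainamide 2 (-0.70, 0.0324), neutrophil markers without BN procainamide 1 (0.30, 0.0189), and connective, epithelial, muscle and eye genes without BN procainamide 3 (-0.26, 0.0434). Complement genes rose in 5 of 15 and fell in 3 (5 and 5 adjusted over the list alone), with C2 2.69-fold higher. Their median was -0.14 while their mean was 0.11. Eosinophil, basophil and mast cell markers fell in 4 of 16 and rose in 2 (6 and 2 adjusted over the list alone; median -0.78, adjusted p = 0.238). Prg3 was 4.90-fold lower, the eotaxin receptor Ccr3 3.93-fold lower and the histidine decarboxylase gene Hdc 3.01-fold higher. Monocyte markers rose in 3 of 16, with Lyz2 at 2.44-fold, and fell in 1, and neutrophil markers rose in 2 of 22, with Mmp9 at 1.96-fold, and fell in 1. MHC class II genes rose in 2 of 14 and fell in 1, their transactivator Ciita rising 1.76-fold. Th17 and regulatory T cell genes rose in 3 of 10 and fell in 1, with Il21 at 2.34-fold. Th2 genes rose in 1 of 9 and fell in 1, and Toll-like receptor genes rose in 3 of 18 and fell in 1. Apoptosis and clearance genes rose in 4 of 20, immediate early genes rose in 2 of 18 and fell in 2, and cell cycle genes rose in 1 of 22 and fell in 1 (median 0.04, mean -0.05). B cell markers fell in 1 of 15, erythroid markers in 2 of 22, glucocorticoid response genes in 2 of 12, with Ddit4 2.58-fold lower, and drug metabolism genes in 2 of 21. Connective, epithelial, muscle and eye genes fell in 4 of 15. In the DNA methylation machinery Tet3 fell (log2 -0.58) among 8 genes (median 0.08, mean -0.06). Of 7 T cell genes known to rise when DNA methylation is inhibited, Itgal rose (1.82-fold) and Il13 fell (1.20-fold).

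In all, 2030 probes rose and 3727 fell in BN blood out of 26446 tested, 1222 and 1883 named genes among 13601 (limma, adjusted p under 0.05). Of the 5757 probes called, 35.3% were higher; the share was 46.7% of the calls on the authors' deposited log ratios and 47.5% with Cy5 alone. With scan day as a term 209 probes passed, 182 of them called before, and the median SE rose from 0.134 to 0.214. With brightness as a term 685 passed, 650 of them called before (median SE 0.175).

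**Figure D1:**
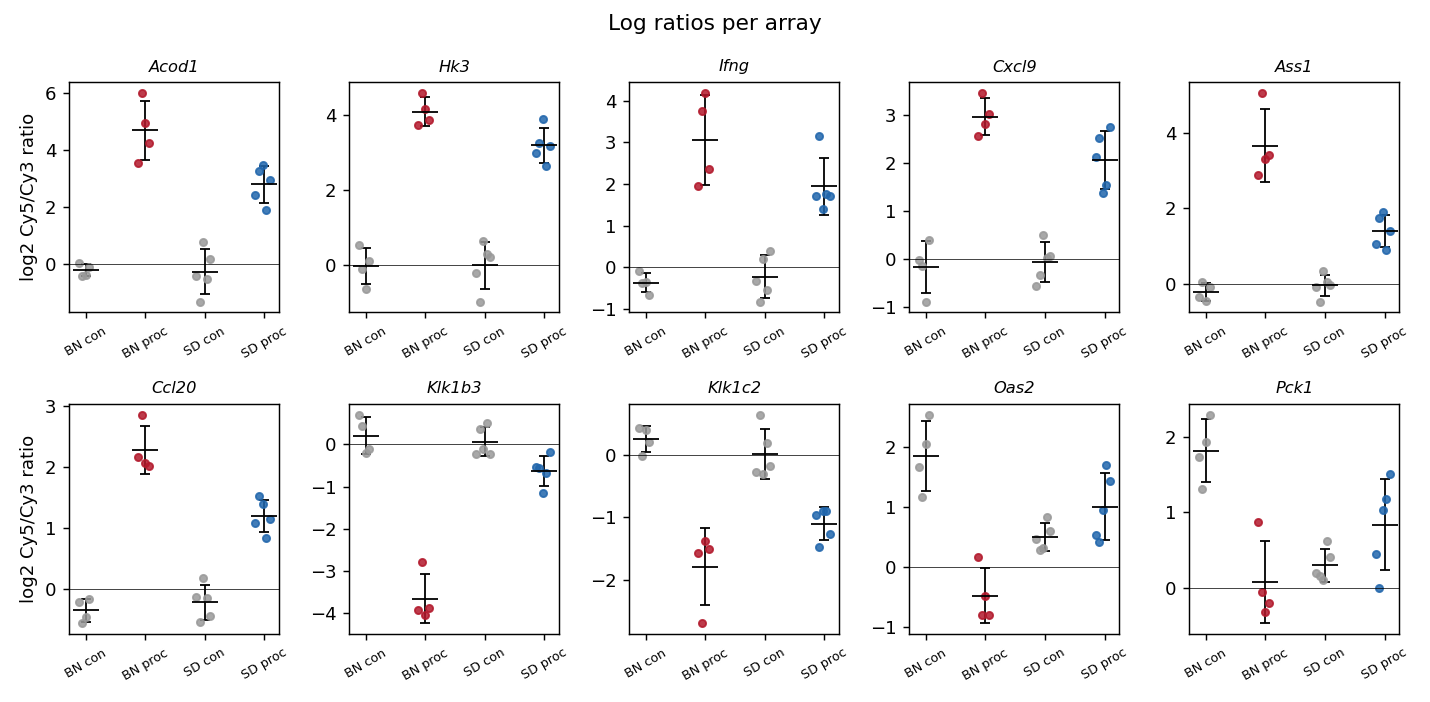
Log2 ratios of Cy5 over Cy3 on each array for 10 of the genes named, by group. Points are arrays, and bars give the mean and SD of 4 BN or 5 SD arrays. Hk3, Acod1, Ifng and Cxcl9 were higher on every procainamide array than on every control array of the same strain, a condition of the rule that chose them.

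The same question in SD rats rested on 5 treated and 5 control arrays. Hk3 rose 9.18-fold (log2 3.20 ± 0.29 SE, adjusted p = 6.85e-05), Acod1 8.31-fold (3.06 ± 0.42, adjusted p = 0.00137), Ifng 4.49-fold (2.17 ± 0.39, adjusted p = 0.00712) and Cxcl9 4.38-fold (2.13 ± 0.28, adjusted p = 0.00111). The monocyte chemoattractant Ccl2 rose 2.97-fold (1.57 ± 0.24), the lymphoid chemokine Ccl19 2.81-fold (1.49 ± 0.17) and Ass1 2.70-fold (1.44 ± 0.31). Capn3, a calpain protease of muscle, fell 3.77-fold (-1.91 ± 0.27, adjusted p = 0.00161), Mgp, an inhibitor of calcification, 2.25-fold (-1.17 ± 0.18) and the gap junction gene Gjb2 2.18-fold (-1.13 ± 0.17). Gpr84 (3.02-fold, 1.60 ± 0.32) also rose and Klk1c2 (2.17-fold, -1.12 ± 0.23) also fell. With slide as a block, which in SD is the same as scan day as a term, these genes kept their direction and stayed past the threshold, except Klk1c2 (adjusted p = 0.0627).

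Other genes among the 20 named in SD did not stay past the threshold with slide as a block, although their sizes hardly moved and their SEs rose. Ubd rose 4.34-fold (log2 2.12 ± 0.49 SE, adjusted p = 0.0263; 2.06 ± 0.58 and 0.113 with the block). Mfap4 fell 2.54-fold (-1.34, 0.0264; -1.41, 0.0851), Cd300le 2.22-fold (-1.15, 0.0355; -1.15, 0.125), Mal 2.21-fold (-1.14, 0.0245; -1.17, 0.0880), Tac3 2.19-fold (-1.13, 0.0220; -1.13, 0.0866) and Cd300c2 2.16-fold (-1.11, 0.0355; -1.14, 0.114). With brightness as a term 13 of the 20 stayed past it.

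In SD blood 6 gene lists shifted higher and 5 lower by camera, and the same 11 did so with slide as a block; of these, the NF-kB and platelet lists had under 80% of their genes measured. None of them passed with an estimated correlation, where limma's camera gave 7 lists with an unadjusted p under 0.05. MHC class I genes rose in 6 of 12 members (10 adjusted over the list alone; median 0.49, adjusted p = 8.68e-11; adjusted p = 0.0635 with an estimated correlation), including Psmb9, a subunit of the immunoproteasome (1.89-fold), and Tap1 (1.68-fold). Interferon response genes rose in 8 of 26 (15 higher and 1 lower adjusted over the list alone; median 0.47, adjusted p = 1.43e-10; adjusted p = 0.179 with an estimated correlation), including Gbp2 (2.08-fold) and Oasl2 (1.88-fold). Cell cycle genes rose in 2 of 22, Kif11 (1.54-fold) and the replication licensing gene Mcm2 (1.49-fold), and in 13 adjusted over the list alone (median 0.45, adjusted p = 6.47e-10; adjusted p = 0.271 with an estimated correlation). Oxidative phosphorylation genes rose in 1 of 42 (1 adjusted over the list alone; median 0.11, adjusted p = 0.00109; adjusted p = 0.329 with an estimated correlation). NF-kB targets rose in 3 of 16, Ccl2, Ccl4 (1.94-fold) and Icam1 (1.30-fold), and in 4 adjusted over the list alone (median 0.32, adjusted p = 0.00292; adjusted p = 0.206 with an estimated correlation). Th1 genes rose in 2 of 7, Ifng and Cxcr3 (1.40-fold), and in 3 adjusted over the list alone (median 0.22, adjusted p = 0.00694; adjusted p = 0.0635 with an estimated correlation).

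Glucocorticoid response genes fell in 2 of 12, Fkbp5 (1.47-fold) and Anxa1 (1.44-fold), and in 3 adjusted over the list alone (median -0.33, adjusted p = 0.00250; adjusted p = 0.0635 with an estimated correlation). Endothelial markers fell in 1 of 8, Kdr (1.42-fold), and in 2 adjusted over the list alone (median -0.30, adjusted p = 0.0105; adjusted p = 0.179 with an estimated correlation). Connective, epithelial, muscle and eye genes fell in 1 of 15, the collagen gene Col1a2 (1.54-fold), and in 2 adjusted over the list alone (median -0.25, adjusted p = 0.0224; adjusted p = 0.179 with an estimated correlation). No single member passed over all genes in the platelet list (0 of 13; 5 lower adjusted over the list alone; median -0.37, adjusted p = 0.00223; adjusted p = 0.271 with an estimated correlation). The same held for drug metabolism genes (0 of 21; 3 lower adjusted over the list alone; median -0.19, adjusted p = 0.0208; adjusted p = 0.266 with an estimated correlation). With brightness as a term the drug metabolism list (adjusted p = 0.0772) and the connective tissue list (adjusted p = 0.0510) were lost and T cell markers passed (median 0.16, adjusted p = 0.0107). By fry the lists of cell cycle (adjusted p = 0.0536), oxidative phosphorylation (0.0590) and drug metabolism (0.0590) did not pass. By camera with 1 array left out, the connective tissue list did not pass without SD control 3 (0.0511) or SD procainamide 2 (0.0639), and the drug metabolism list did not without SD control 3 (0.0550), while T cell markers passed without SD control 2 (median 0.12, adjusted p = 0.0340), SD control 3 (0.17, 0.0389) or SD procainamide 3 (0.16, 0.0165). Among lists without a shift, complement genes rose in 2 of 15, C2 by 2.43-fold, and fell in 1, NK cell genes rose in 3 of 16, Klrc1 by 1.74-fold, and the immediate early genes Klf4 and Nr4a1 each fell 1.59-fold.

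In all, 359 probes rose and 368 fell in SD blood, 193 and 239 named genes. The count of 727 became 254 with slide as a block (243 called before), 344 on slide 1 alone and 419 with brightness as a term. It was 234 without SD control 2, 336 without SD procainamide 5, 354 without SD procainamide 2, 368 without SD control 4, 410 without SD control 1, 422 without SD procainamide 4, 431 without SD control 5 and 450 without SD procainamide 3.

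Both strains were then set side by side. Probes called higher in both numbered 176, where independent lists would share 27.6, and probes called lower in both 192, where they would share 51.9. Of the probes called in SD, 83.2% had the same sign in BN, and on slide 1 alone, where both SD groups shared a slide and a scan, the share was 95.1% of 344. Across all probes, which are not independent replicates, the log2 differences of the strains correlated at r = 0.192 (rho = 0.04), and at r = -0.26 with Cy5 alone in place of ratios.

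**Figure D2:**
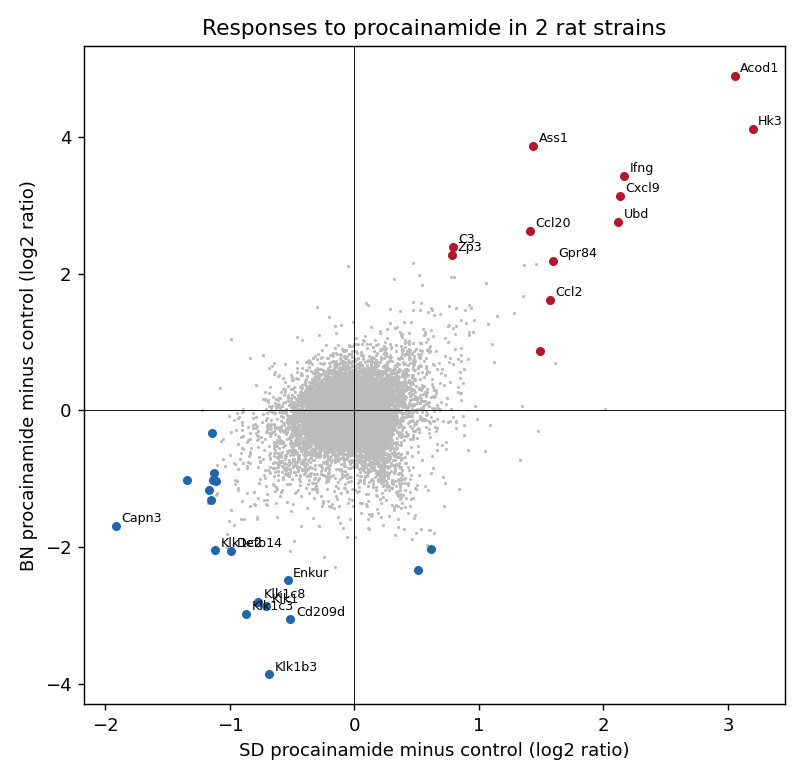
Log2 difference between procainamide and control in BN rats (vertical axis) against that in SD rats (horizontal axis), with a grey point for each named gene tested. Coloured points are the genes reported for the responses, red where higher and blue where lower in BN; Hk3 and Acod1 lie at the upper right and Klk1b3 at the bottom.

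**Figure D3:**
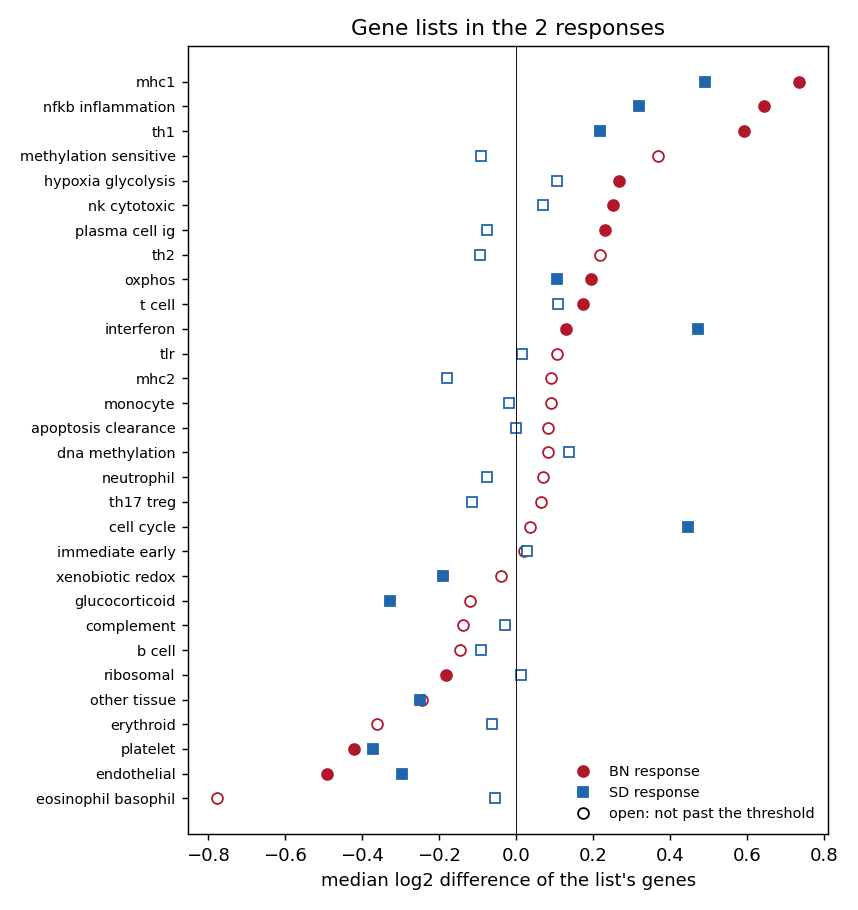
Median log2 difference of each of the 30 gene lists in the BN response (circles) and the SD response (squares). Filled symbols passed camera's adjusted threshold, and MHC class I genes passed in both strains, at 0.73 and 0.49 (adjusted p = 0.145 and 0.0635 with an estimated correlation).

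A test of the difference itself asked where the strains' responses diverged. The falls of 4 kallikrein genes were larger in BN than in SD. The difference was -3.17 ± 0.37 (log2, SE, adjusted p = 0.000827) for Klk1b3, whose SD difference was -0.69 and did not pass, -2.16 for Klk1, -2.11 for Klk1c3 and -2.02 for Klk1c8. For Klk1c2 it did not pass (-0.93, adjusted p = 0.0899). For Cd209d the difference was -2.54 ± 0.38 (adjusted p = 0.00132), but it was well above background on 2 of 5 SD control and 0 of 5 SD procainamide arrays, so a larger fall in SD was not measurable. Rises were larger in BN for Ass1 (2.43 ± 0.46, adjusted p = 0.00363) and Zp3 (1.49 ± 0.25, 0.00217; well above background on 2 of 4 BN and 1 of 5 SD control arrays, so that its size is not exact). Genes that rose in BN and did not pass in SD were the inhibitory receptor gene Lilrb4 (difference 2.04 ± 0.42, adjusted p = 0.00560; SD difference -0.99), C3 (1.60 ± 0.33, 0.00588; SD difference 0.79, adjusted p = 0.0631), the chitinase-like gene Chi3l1 (1.81 ± 0.41, 0.00929), Dnase2b (1.60 ± 0.46, 0.0325), Rnase10 (1.45 ± 0.36, 0.0159) and the succinate receptor gene Sucnr1 (1.43 ± 0.44, 0.0449). Sucnr1 was well above background on 1 of 4 BN control and 2 of 5 SD control arrays, so the size of its difference is not exact. The neutrophil chemokine receptor gene Cxcr2 differed by 1.60 ± 0.39 (adjusted p = 0.0132), with differences of 0.76 in BN and -0.84 in SD that did not pass in either strain.

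The other genes with a large negative difference fell in BN and lay between 0.46 and 0.61 in SD, where they did not pass. They were Oas2 (-2.84), Scart1 (-2.64), the small heat shock protein gene Hspb3 (-2.55), the importin gene Kpna5 (-2.35), the hedgehog receptor gene Ptch1 (-2.35), Enpp7 (-2.34), the mitochondrial anchoring protein gene Akap1 (-2.28) and Pck1 (-2.27), which encodes an enzyme of gluconeogenesis. Akap1 and Scart1 each had another probe, and it was not called. Genes such as Hspb3 were higher in log2 ratio on the BN control arrays (1.93 ± 0.56 SD, n = 4) than in the other groups, and those arrays were on slide 2. On the 2 SD procainamide arrays of slide 2 Hspb3 read 1.44 and 1.33, and on the 3 of slide 1 between 0.25 and 0.65.

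By camera, NF-kB targets (median difference 0.53, adjusted p = 0.00307; adjusted p = 0.492 with an estimated correlation) and Th1 genes (0.36, adjusted p = 0.0230; adjusted p = 0.260 with an estimated correlation) shifted higher in BN than in SD, the NF-kB value being for the 16 of 21 genes measured. Among NF-kB targets 4 of 16 differed (5 adjusted over the list alone), such as Il1rn (0.96) and Ccl3 (0.83), and among Th1 genes 1 of 7, Il2 (0.43), with 2 adjusted over the list alone. Cell cycle genes (median -0.50, adjusted p = 0.00307; adjusted p = 0.673 with an estimated correlation) shifted the other way in 4 of 22 members (4 adjusted over the list alone), Birc5 (-1.16), Cdc20 (-1.04), Mcm2 (-0.71) and Mcm4 (-0.65). So did ribosomal protein genes (median -0.19, adjusted p = 0.00583; adjusted p = 0.673 with an estimated correlation), in 4 of 46 members and 9 adjusted over the list alone. With scan day as a term the cell cycle (adjusted p = 0.000943) and ribosomal (0.00646) lists stayed past the threshold, while NF-kB targets (median 0.16, adjusted p = 0.134) and Th1 genes (0.29, 0.0750) did not. MHC class I (0.46, adjusted p = 0.00392), MHC class II (0.56, 0.00408), plasma cell (0.60, 0.00668) and apoptosis and clearance genes (0.29, 0.0315) then passed. With brightness as a term NF-kB targets were lost (adjusted p = 0.150) and interferon response genes passed with a median of -0.39 (adjusted p = 0.0185). By fry cell cycle genes did not pass (adjusted p = 0.279), and Th2 genes were higher (median 0.34, adjusted p = 0.0382). By camera Th1 genes did not pass without BN control 1 (adjusted p = 0.0603) or SD procainamide 1 (0.0548), and cell cycle genes did not without BN control 1, where their median went from -0.50 to -0.26 (0.0630). Other lists passed with 1 array left out. NK cell genes did so without BN control 2, BN procainamide 1 or 4, SD control 4 or SD procainamide 5 (medians 0.24 to 0.34), plasma cell genes without BN control 2, BN procainamide 3 or SD procainamide 5 (0.32 to 0.59), and oxidative phosphorylation genes without BN procainamide 1 or 4 or SD procainamide 3 (0.09 to 0.12). Without BN procainamide 1 neutrophil markers (0.41, adjusted p = 0.0152) and MHC class I genes (0.31, 0.0393) passed too.

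The responses differed in 2948 probes, 684 with a positive and 2264 with a negative difference, so that 23.2% were positive; with Cy5 alone 46.4% of 9372 were. With scan day as a term limma called 0 probes, with 1528 at an unadjusted p under 0.05, and none of the 20 named genes passed, although all kept their direction (adjusted p = 0.574 for Klk1b3, the lowest). The median SE rose from 0.180 to 0.295. Sizes changed little for Klk1b3 (-3.17 to -2.73), Cd209d (-2.54 to -2.48), Lilrb4 (2.04 to 2.10), Chi3l1 (1.81 to 2.10) and C3 (1.60 to 1.56), and shrank more for Scart1 (-2.64 to -0.89), Ptch1 (-2.35 to -0.66), Kpna5 (-2.35 to -0.95), Enpp7 (-2.34 to -1.01), Cxcr2 (1.60 to 0.69), Hspb3 (-2.55 to -1.16), Akap1 (-2.28 to -1.08) and Pck1 (-2.27 to -1.09). With brightness as a term 6 probes passed, including Klk1b3 and Cd209d (both adjusted p = 0.0467). The differences were then -3.62 for Klk1b3, -3.23 for Cd209d and 1.39 for C3, but 1.49 for Lilrb4 and 0.98 for Chi3l1. Chi3l1 thus held its size with scan day and not with brightness. The count was 1882 without BN control 4.

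**Figure D4:**
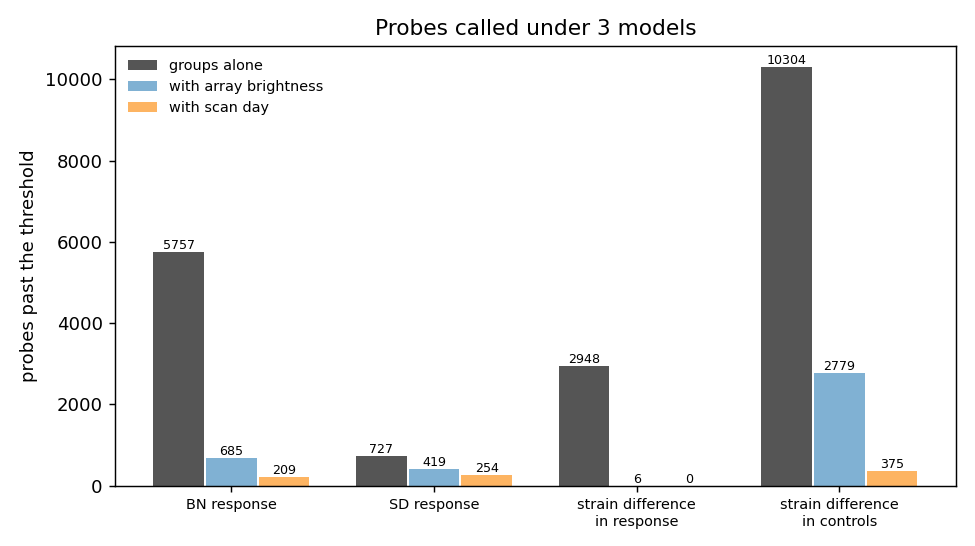
Number of probes past the adjusted threshold in each comparison with the groups alone, with array brightness as a term and with scan day as a term. The strain difference in response went from 2948 to 6 and 0 probes.

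The last comparison asked how untreated BN rats (4 arrays) differed from untreated SD rats (5 arrays). It used Cy5 alone because by the labels the strains had different references. All BN control arrays lay on slide 2 and all SD control arrays on slide 1, so strain coincided with slide and scan day. The probes were not checked against the sequence of either strain, so a difference in binding cannot be told from one in expression. Across probes the BN response in Cy5 alone correlated at r = 0.606 with the Cy3 difference between slides 3 and 2. For the log2 ratios this r was -0.0294. The noncoding RNA gene AA926063 was 45.4-fold higher in BN (log2 5.50 ± 0.17 SE, adjusted p = 5.99e-13), the drug-metabolising cytochrome P450 genes Cyp2d5 17.6-fold (4.14 ± 0.13) and Cyp2d1 15.9-fold (3.99 ± 0.14), and Echdc2 11.6-fold (3.54 ± 0.11). Echdc2 was well above background on 1 of 5 SD control arrays, so its size is not exact. The salt-inducible kinase gene Sik1 was 60.9-fold lower in BN (-5.93 ± 0.17, adjusted p = 3.55e-13), the growth factor gene Vegfb 16.5-fold (-4.05 ± 0.50) and the transcription factor gene Ascl3 12.5-fold (-3.64 ± 0.12). Retnla was not well above background on any BN control array and was at least 17.0-fold lower there (adjusted p = 1.07e-05). The MHC class II alpha chain gene RT1-Ba was 6.38-fold lower (-2.67 ± 0.16), and the integrin gene Itgal 6.39-fold lower (-2.68 ± 0.24).

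Cd209d was 9.62-fold higher in BN controls (well above background on 2 of 5 SD arrays, so its size is not exact), Bcl2l15 9.24-fold, Gpr15lg 8.51-fold, the lectin gene Itln1 7.14-fold, Enpp7 6.36-fold and Atp6ap1l 5.92-fold. The phosphodiesterase gene Pde6b was 8.27-fold lower, the embryonic globin gene Hbe1 7.04-fold, Btnl5 6.94-fold and Gpat2 6.26-fold. Of these, Pde6b, Hbe1 and Gpat2 were well above background on 2 and Btnl5 on 1 of the 4 BN control arrays, so their sizes are not exact. Another probe of Btnl5 was not called. With slide as a block, estimated through the SD procainamide arrays, 18 of the 20 named genes stayed past the threshold. Enpp7 did not, its log2 difference going from 2.67 to 0.81 (adjusted p = 0.343), and Pde6b turned from -3.05 ± 0.57 to 0.12 ± 0.21 (adjusted p = 0.848). Pde6b read 7.13 ± 0.22 (log2 Cy5, SD) on the BN control arrays, on slide 2, and 10.24 ± 0.20 on the BN procainamide arrays, on slide 3. By themselves these BN readings do not tell drug from slide. The slide block rests on the SD procainamide arrays alone, which share strain and drug, and it took up the whole difference of Pde6b. Its 8.27-fold value is therefore not shown to be a strain difference.

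By camera 4 lists were higher in BN controls and none lower. Platelet markers (13 of 18 genes measured) were higher in 9 of 13 members (9 adjusted over the list alone; median 0.57, adjusted p = 1.92e-05; adjusted p = 0.501 with an estimated correlation), among them Selp, the gene of P-selectin (4.69-fold), F13a1 (2.08-fold) and Gp5 (2.02-fold). Interferon response genes were higher in 9 of 26 (9 adjusted over the list alone; median 0.29, adjusted p = 0.000414; adjusted p = 0.928 with an estimated correlation), including Oas2 (4.96-fold), Ifit3 (2.31-fold) and Irf7 (1.84-fold). Cell cycle genes were higher in 4 of 22 (4 adjusted over the list alone; median 0.31, adjusted p = 0.00224; adjusted p = 0.928 with an estimated correlation), including Birc5 (2.54-fold) and Plk1 (1.79-fold). Neutrophil markers were higher in 10 of 22 and lower in 1 (10 and 3 adjusted over the list alone; median 0.47, adjusted p = 0.0392; adjusted p = 0.928 with an estimated correlation). The neutrophil granule genes RatNP-3b (3.71-fold), Prtn3 (3.35-fold) and Np4 (3.17-fold) were among them. All 4 lists passed with slide as a block too, where B cell markers (median -0.33, adjusted p = 0.0185) and Th2 genes (-0.14, 0.0430) were lower. By fry the neutrophil (adjusted p = 0.0957) and cell cycle (0.127) lists did not pass. Without BN control 1 the number of lists past the threshold was 2, the neutrophil (adjusted p = 0.138) and cell cycle (0.350) lists being lost, and the cell cycle median went from 0.31 to 0.05. Neutrophil markers did not pass without BN control 2 (0.0589), SD control 1 (0.0702) or SD control 4 (0.0800) either.

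Fry called 4 other lists lower in BN controls: Th17 and regulatory T cell genes (adjusted p = 0.000112), Th2 genes (0.000114), methylation-sensitive T cell genes (0.00410) and MHC class II genes (0.0208). Th2 genes were lower in 3 of 9, Il4 2.63-fold, Ccr4 2.52-fold and Gata3 1.45-fold, and Th17 and regulatory T cell genes in 3 of 10, Tnfrsf18 1.93-fold, Ctla4 1.88-fold and Ccr6 (log2 -0.58). In the MHC class II list RT1-Bb was 1.74-fold higher while RT1-Ba was lower. Drug metabolism genes were lower in 5 of 21, including the N-acetyltransferase genes Nat1 (1.35-fold) and Nat3 (1.28-fold), and higher in 1. Eosinophil, basophil and mast cell markers were higher in 4 of 16, with Rnase3 at 3.67-fold, and lower in 1, Ccr3. Complement genes were lower in 3 of 15, C3 by 1.93-fold. The control groups differed in 10304 probes, 5461 higher and 4843 lower in BN, and 375 (360 of them called before) passed with slide as a block, where the median SE rose from 0.132 to 0.206. With slide as a random block 4489 passed, and 2779 with brightness as a term.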

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

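The explanations by slide for the remaining BN calls, by Cy5 brightness, by spread and by the reference channel were tested only after the result was seen. The responses of the strains differed by a test of the difference itself in 2948 probes. The named genes reported among them were Klk1b3 (-3.17), Oas2 (-2.84), Scart1 (-2.64), Hspb3 (-2.55), Cd209d (-2.54), Kpna5 (-2.35), Ptch1 (-2.35), Enpp7 (-2.34), Akap1 (-2.28), Pck1 (-2.27), Klk1 (-2.16), Klk1c3 (-2.11), Klk1c8 (-2.02) and Enkur (-1.95). With the opposite sign they were Ass1 (2.43), Lilrb4 (2.04), Chi3l1 (1.81), Cxcr2 (1.60), Dnase2b (1.60), C3 (1.60), Zp3 (1.49), Rnase10 (1.45), Sucnr1 (1.43) and Ccl20 (1.21). The sizes for Cd209d, Zp3, Sucnr1 and Ccl20 are not exact, since these were near background on several arrays (Ccl20 on 3 of 5 SD control arrays); for Cd209d this held on all 5 SD procainamide arrays, so a larger fall in SD was not measurable. The list medians were 0.53 for NF-kB targets (16 of 21 genes measured; adjusted p = 0.492 with an estimated correlation), 0.36 for Th1 (0.260), -0.50 for cell cycle (0.673; median -0.26 without BN control 1) and -0.19 for ribosomal protein genes (0.673). NF-kB targets (median 0.16, adjusted p = 0.134) and Th1 genes (0.29, 0.0750) did not pass with scan day as a term. With scan day as a term the median SE of the difference in response rose from 0.180 to 0.295, and 0 probes passed (limma, 1528 at an unadjusted p under 0.05). Klk1b3 (-2.73), Cd209d (-2.48), Lilrb4 (2.10) and C3 (1.56) then stayed about as large. Scart1 (-0.89) and Ptch1 (-0.66) were much smaller, and Oas2 (-1.54) and Zp3 (0.82) were smaller too.

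More probes were called in BN than in SD, and BN control and BN procainamide arrays lay on different slides. A slide difference alone is excluded for the probes called on slide 1 in SD, 95.1% of which had the same sign in BN. For the other 5527 BN calls the slide explanation fits: 78.8% were opposite in sign to the difference of slide 2 from slide 1 among SD procainamide arrays, against 63.1% of all probes. A shift of the reference channel passing into the ratios across all probes is excluded (r = -0.0294). The called probes were not tested apart, so such a shift is not excluded for single ones. The spread was not smaller in BN (ratio of SDs 1.29). Since the model shared 1 spread over all groups, that ratio does not tell whether spread bears on the excess. With only each strain's own arrays 2801 probes were called in BN (median SE 0.145) and 1486 in SD (0.102). Dimmer Cy5 on the BN control arrays stays open (61.1% of BN calls had the sign of the brightness slope within slide 1). The SD procainamide arrays of slide 2 were also dimmer in Cy5 (medians 1655 and 1446) than those of slide 1 (2530, 2627.5 and 1700), so the comparison of signs does not tell slide from brightness. How much of the BN count is a response to the drug stays open.

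A chance division of these arrays can be excluded as the origin of the counts for the BN response, the SD response and the controls. In each, 1 split, the real one, gave as many calls, in BN the least that 35 splits allow. Whether each array came from a separate animal is not stated, so this does not cover chance between animals. In BN and in the controls the real split was also the split by slide. There the splits do not tell drug or strain from slide. The real and highest other counts were 5757 and 3302 of 35 splits in BN, 727 and 1 of 100 in SD, and 10304 and 5175 of 100 for the controls. For the difference in response they were 2948 and 2834 of 100, again with 1 split, the real one, as high. That highest other split kept the BN groups and reshuffled SD arrays, so these splits ask whether either strain responded and do not show that the responses differ.

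In Cy3, which by the labels held the same RNA on both slides, 14448 probes differed between slides 3 and 2 in BN, a signal in a channel that the comparisons did not test. Single arrays far from the others of their group were found in 11 of 204 groups, and chance gives about 1 in 20. Those reported were BN procainamide 2 for Klk1b3 (log2 ratio -2.78) and Klk1c2 (-2.70), SD procainamide 2 for Ifng (3.15), SD control 3 for Ccl2 (0.69), SD control 2 for Capn3 (0.83), SD procainamide 3 for Cd300c2 (-1.32), SD control 4 for Ptch1 (1.17), and in log2 Cy5 SD control 2 for Sik1 (13.50) and BN control 4 for Vegfb (11.72). BN procainamide 1 stood apart in the percentage of spots marked by the software (1.43).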

How the results depend on the processing

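Scan day and array brightness were chosen as terms only after the results had been seen; every other alternative was planned. The BN count of 5757 probes became 209 with scan day, 685 with brightness, 10399 with Cy5 alone, 3581 with a replicate block, 2801 with only BN arrays and 681 at a fold change of at least 2. It stayed between 4786 and 7276 under the other planned settings that kept all 18 arrays. The SD count of 727 became 254 with scan day or slide as a fixed block, 344 on slide 1 alone, 419 with brightness, 128 with a replicate block, 2601 with array weights, 1486 with only SD arrays and 65 at a fold change of at least 2. Of the SD calls 49.4% were higher, and 60.1% with trend and robust eBayes. The strain difference in response, 2948 probes, became 0 with scan day (limma, 1528 at an unadjusted p under 0.05), 6 with brightness (2533 unadjusted), 1965 with scaling between arrays, 9372 with Cy5 alone, 1364 with a replicate block and 667 at a fold change of at least 2. The difference in controls, 10304 probes, became 375 with scan day or slide as a fixed block, 4489 with slide as a random block, 2779 with brightness and 1260 at a fold change of at least 2. Fewer probes can pass a fold minimum by construction. With scan day the median SE in BN rose from 0.134 to 0.214, and the sizes of some named genes shrank. How much each contributed was not tested, nor was the cause for the other settings.

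Gene list shifts with an estimated correlation numbered 2 of 12 in BN, 0 of 11 in SD (7 at camera's unadjusted p under 0.05), 0 of 4 for the strain difference in response (2 unadjusted) and 0 of 4 for the controls (2 unadjusted). By fry they numbered 15 in BN, 8 in SD, 4 and 6. With Cy5 alone they numbered 5 in BN and 0 for the difference in response (4 unadjusted). The correlation of the strains' responses reversed from 0.192 to -0.26 with Cy5 alone, and the cause was not tested. Pde6b in the controls went from -3.05 to 0.12 with scan day or slide as a fixed block, a term that rests on the SD procainamide arrays.

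Leaving out each array gave 3936 to 6497 probes in BN, 234 to 982 in SD, 1882 to 3824 for the difference in response and 8623 to 10395 for the controls. The SD count moved without SD_control replicate 1 (410), 2 (234), 4 (368) and 5 (431) and without SD_procainamide replicate 2 (354), 3 (450), 4 (422) and 5 (336), and the difference in response without BN_control replicate 4 (1882). List shifts numbered 9 to 13 in BN, 10 to 12 in SD, 2 (without BN_control replicate 1) to 8 (without BN_procainamide replicate 1) for the difference in response and 2 (without BN_control replicate 1) to 4 for the controls. Of the named genes' values with an array left out, the call was lost in 0 of 360 in BN, 57 of 360 in SD (9 genes, such as Cd300le and Mal), 22 of 360 for the difference in response (Sucnr1 and Dnase2b) and 0 of 180 for the controls. By the labels the Cy3 channel of the controls holds 1 RNA per strain, so its comparison was not run as a test.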

Other observations

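The gene lists in this part were chosen only after the named genes' results were seen, and before the lists' own values were. Genes induced by interferon gamma and outside the fixed lists rose in both strains: 14 of 19 measured in BN (median 0.88, adjusted p = 1.62e-10; adjusted p = 0.0761 with an estimated correlation) and 6 of 19 in SD (median 0.41, adjusted p = 1.50e-09; adjusted p = 0.0926 with an estimated correlation). Irf1 (log2 1.47 in BN, 0.89 in SD), Gbp5 (1.54, 0.92), Irgm (1.38, 1.15) and the tryptophanyl-tRNA synthetase gene Wars1 (1.25, 0.76) rose in both. The tryptophan-degrading enzyme gene Ido1 (1.57), the checkpoint ligand gene Cd274 (1.23) and the superoxide dismutase gene Sod2 (1.14) rose in BN and did not pass in SD. As an explanation an interferon gamma response fits by camera at the preset correlation, the lower of the 2 strains' medians being 0.406. Whether other signals induced these genes was not tested. Classical macrophage activation stays open, since only 77.8% of its list was measured. Of the 14 genes measured, 3 rose in BN (median 0.326, camera's adjusted p = 0.0177, and 0.349 with an estimated correlation). In SD 0 passed and the measured genes did not shift (median 0.149, camera's adjusted p = 0.336, and 0.811 with an estimated correlation).

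Kallikrein genes beyond those named fell as well: Klk1c9 (log2 -1.03 in BN, -0.94 in SD) and Klk1c12 (-0.66, -0.56) passed in both strains, while Klk1c10 (-0.16 in BN, adjusted p = 0.424) did not. A shift of the reference channel is excluded as the cause of the whole fall. The median Cy3 difference of the family between slides 3 and 2 was 0.381 beside a median fall of -2.42. It was largest for Klk1c2 (0.60 beside -2.05), so a part of the falls can still come from this shift. For less gland tissue in the samples the test is void, since only 54.5% of the list of exocrine gland genes was measured, so it stays open. The 12 genes measured had a median of 0.113 in BN and lay between -0.29 and 0.80, with 3 higher and 0 lower at limma's adjusted threshold (also 3 and 0 at an unadjusted p under 0.05). Cross-hybridisation between near-identical family members also stays open, with a median pairwise correlation of 0.730 over the arrays.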
